A study of Mus musculus with 3 samples.

How the data were processed

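The samples were 3 RNA-seq libraries, labelled replicates 1, 2 and 3, of the mouse cell line IDG-SW3 at day 35 of differentiation, after 24 h with 100 nM parathyroid hormone (PTH). Per the series' design text, the replicates were biological. IDG-SW3 is an osteocytic line that is expanded with interferon-gamma at the lower temperature that keeps its conditional T antigen active, and is then differentiated without interferon-gamma at body temperature in osteogenic medium. Per the labels' protocols, ribosomal RNA was depleted from total RNA and strand-preserving libraries were made with the ScriptSeq kit, so transcripts without a poly(A) tail were also captured. The 3 libraries form 1 group. The vehicle-treated libraries that the design text names belong to another series and were not analysed here. The effect of PTH on any gene was therefore not measured, and each comparison below sets genes of the same libraries against a fixed level or against each other.

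Each deposited file listed a whole number for each of 30795 transcript rows, named by gene symbol. The file names give the unit as RPKM, but the values were read as counts. They were whole numbers that summed to 35195518, 37299517 and 45240005 in replicates 1, 2 and 3. Multiplied by transcript length in kilobases they summed to 111182696, 118279595 and 144704449, where RPKM values allow about 1000000. The deposited values were used as raw counts of reads per transcript row, with no normalization. Another whole-number quantity is not excluded, since the counting step is not described, and every RPKM and counting interval rests on this reading. Per the submitters' processing notes, TopHat and the mouse build mm9 were used; their versions, the counting tool, the gene annotation and the treatment of strand, duplicates and reads with several matches are not given in the sources used here. No row lacked a gene name, and 25 symbols had been turned into dates.

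The rows held 25410 symbols, 21940 with 1 row and 3470 with several. Rows of a symbol were summed; the plan written before the data were examined had been to average them, which assumed RPKM values. Symbols with several rows were often at or near 0 even where every cell uses the gene, so a low value of such a gene is not read as absence, and results over symbols with 1 row are given beside the others. Lengths were the median over the basic transcripts of GENCODE M21 (build GRCm38), with 20840 symbols matched directly and 2177 through RefSeq synonyms. These 23017 symbols, 90.6% of all, held 96.4%, 96.4% and 96.3% of the counts, and the other 2393 were left out. The files hold no coordinates and the authors' build differs from the annotation's, so no positions are printed. RPKM was computed here as counts per kilobase and per 1000000 counts of all rows, and is given as mean ± SD over the 3 libraries (n = 3).

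Because the values were read as counts, each gene's level was tested two-sided against 1 RPKM with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with trended dispersion and robust estimation, the expected count at 1 RPKM as offset, and a Poisson bound on p. The F statistic of the single coefficient was computed from the edgeR fit. This replaced the limma test planned for RPKM values, which was kept as an alternative (limma 3.58.1). Genes above 0 in at least 1 library were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is called above or below 1 RPKM where it passed, and unresolved where it did not. Gene pairs were fixed beforehand, 22 in number, and the within-library difference of log2(RPKM + 0.1) was tested against 0 with limma, adjusted over the pairs. The p-value of a pair measures agreement among libraries. It does not cover a counting or sequence bias of a gene that all libraries share. Folds on this scale are understated for low genes. The exact sign-flip permutation test cannot give a p below 0.25 with 3 libraries. Count ratios carry exact 95% binomial intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules; a gene at 0 allows up to 3 counts.

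The 23 gene lists were also fixed beforehand and cover osteoblast and osteocyte genes, PTH signalling, bone processes, housekeeping and RNA classes, and markers of 7 other cell types. For each list the median RPKM is given with its percentile among the medians of 10000 random lists of the same size, as a description. The osteocyte list was compared with each list of another cell type by a two-sided permutation test across genes, which are not independent replicates, with 100000 resamples and adjustment over the 7 lists. Named genes were chosen by a rule written beforehand: all genes of the pairs, up to 4 members of each list with the highest mean RPKM, the 15 genes with the highest mean RPKM, and the 10 genes with the largest SD of log2(RPKM + 0.1) among those with mean RPKM of 5 or more. The 15 highest protein-coding genes and every other gene named in the text were chosen after their values were seen. A few genes that this rule names are not reported here.

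The level test was tried on simulated counts made from the real means and library sizes, with 20465 genes in the fit. The pair and list tests were tried on values drawn from normal distributions. All genes placed at 4 RPKM were called above 1 RPKM (100%), 39% of genes placed at 0.25 RPKM were called below it, and 3.5% of genes placed at 1 RPKM were called either way. The test therefore resolves levels above 1 RPKM far better than levels below it. The pair test called 100% of simulated ratios of 1 on the log2 scale with an SD of 0.15, and 3% of ratios of 0. The real pairs had SDs of up to 2.18. In 500 simulated sets with those SDs, the 14 pairs under an SD of 0.5 were called in 94.8% of cases at a ratio of 1, and the 8 above it in only 38.6%. At a ratio of 0 a set had any call in 7% of cases. A pair with a large SD that did not pass is therefore not shown to be equal. The list comparison passed 2.5% of a small number of simulated pairs of lists with no difference. Those lists held independent values of equal spread, so this says little about real lists of related genes. Alternatives were other pseudocounts, each library left out in turn, other scalings, filters and thresholds, and the highest row per symbol. DESeq2 1.42.0, the mean over rows, other lengths, counts per 1000000 without length, symbols with 1 row and a correction for GC content (lowess, span 0.3) were added after the data were seen. For counts, the mean over rows divides the summed count of a symbol by its number of rows. It therefore lowers symbols with several rows by construction. The GC correction was also applied at 0 counts, where it shifts the pseudocount alone. DESeq2 was given length and depth factors that were not centred on 1, so its dispersion trend was fitted on the RPKM scale. Its calls therefore do not show what a standard DESeq2 run would give. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used for tables and the Fisher test.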

Results

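Gene expression was measured by RNA-seq of ribosomal RNA-depleted total RNA in IDG-SW3 cells, a mouse line that differentiates from late osteoblasts into osteocyte-like cells. The single group held 3 replicate libraries at day 35 of differentiation, treated for 24 h with 100 nM PTH, the hormone that acts on osteoblasts and osteocytes through its receptor Pth1r. The libraries held 35195518, 37299517 and 45240005 counts for replicates 1, 2 and 3. The files name their unit RPKM but hold whole numbers, which were read as counts; every RPKM and counting interval given here rests on that reading. The study asked which transcripts PTH regulates in osteocytes, which needs the vehicle libraries, not analysed here. What the libraries answer is which genes the treated cells expressed and at what level. Values are mean RPKM ± SD, with n = 3 throughout.

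Noncoding RNAs, described with the RNA classes, had the highest levels of all symbols, with Rn7sk first. Among protein-coding genes, Sparc, which encodes the matrix protein osteonectin, was highest at 6409 ± 408 RPKM. The translation factor Eef1a1 followed at 5199.7 ± 144, and the gap junction gene Gja1 (connexin 43) stood at 2986 ± 115. Col1a2, a chain of type I collagen, reached 2946 ± 90.4, and Ibsp (bone sialoprotein) 2052 ± 415. Col3a1 stood at 1657 ± 43.4, Hspa8 at 1809.6 ± 141, and the endoplasmic reticulum proteins Hsp90b1 and P4hb at 1492 ± 122.9 and 1478 ± 98.1. The edgeR quasi-likelihood test placed 9071 of 23017 genes above 1 RPKM and 2807 below it. A further 9105 were unresolved, and 2034 were listed at 0 in all 3 libraries. Among the 19725 genes with 1 row, 8507 were above and 2353 below. The count below fell to 1222 without replicate 1 and to 907 without replicate 2, whereas the count above stayed between 8891 and 9003 with any library left out. DESeq2, added after the data were seen and run with uncentred factors, called 267 below, and the planned limma test 9842. Counts of list members below 1 RPKM, given for each list, rest on the same test, and most but not all of them were smaller without replicate 1 or replicate 2.

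Osteoblast-lineage genes were expressed at high levels, and 12 of 20 were above 1 RPKM, 2 were below and 6 were unresolved. The list's median was 67.2 RPKM, at percentile 100 of random lists. Besides Sparc, Col1a2 and Ibsp, Postn (periostin) stood at 1045 ± 33.9 RPKM. Alpl, the alkaline phosphatase needed for mineralization, stood at 132 ± 12.6, and Spp1 (osteopontin) at 136 ± 5.82. Ibsp exceeded Spp1 14.9-fold (log2 ratio of Spp1 over Ibsp −3.90 ± 0.27, limma adjusted p = 0.000225). The genes called below were Msx2 at 0.237 ± 0.22 and Smpd3 at 0.218 ± 0.19. The counts adjusted over the list alone were 12 above and 3 below. Leaving out any library kept 12 above, while the count below was 0 without replicate 1.

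Collagens and their modifying enzymes were broadly expressed, with 28 of 32 members above 1 RPKM and a median of 75.6 RPKM (percentile 100). All 25 members with 1 row were above. Col5a2 stood at 518 ± 22.2 RPKM, Col12a1 at 356 ± 16.01 and the crosslinking enzyme Lox at 207 ± 12.9. The 3 members at 0 (Loxl4, P4ha2 and Plod2) and Lepre1, the member below, each had several rows. The counts adjusted over the list alone were again 28 and 1, with 0 below without replicate 1 or replicate 2. Col1a1, which pairs with Col1a2 in type I collagen, stood at 488 ± 42.5 RPKM, 6.05-fold lower than Col1a2 (log2 ratio −2.60 ± 0.08, limma adjusted p = 0.000198). It was also 3.40-fold lower than Col3a1 (log2 ratio −1.77 ± 0.16, limma adjusted p = 0.00071). With the correction for GC content, the log2 ratio to Col1a2 was −2.22 and that to Col3a1 −1.01. A counting or sequence bias shared by all libraries is not excluded as a source of these ratios.

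Osteocyte genes covered a wide range of levels, from 156 RPKM for Pdpn to a few counts in 1 library for Sost. In the list, 6 of 14 members were above 1 RPKM, 2 below and 6 unresolved. Pdpn, the podoplanin gene of early osteocytes, stood at 156 ± 27.6 RPKM. Hyou1 stood at 43.8 ± 1.04, Fbln7 at 13.2 ± 0.857 and Phex, the endopeptidase gene mutated in X-linked hypophosphataemia, at 9.05 ± 0.94. Irx5 (6.51 ± 0.78) and the kinase gene Fam20c (1.78 ± 0.24) were the other members above. By contrast, the matrix gene Dmp1 stood at 0.652 ± 0.547, with 77, 115 and 6 counts in replicates 1, 2 and 3. Mepe stood at 0.436 ± 0.216 and the phosphate-regulating hormone gene Fgf23 at 0.266 ± 0.0816, and these 3 genes were unresolved against 1 RPKM. Sost, which encodes the Wnt inhibitor sclerostin, had 2 counts in replicate 1 and 0 in the others, and was unresolved too. The planned limma test called Sost, Mepe and Fgf23 below 1 RPKM (limma adjusted p = 1.22e-07, 0.0156 and 0.00412), and DESeq2 with uncentred factors called Sost below (adjusted p = 0.0435). Kcnk2 (0.368 ± 0.168, 3 rows) and Cd44 (0.102 ± 0.049, 6 rows) were also unresolved, and their row numbers leave these values uncertain. The members below were Ptprz1 (0.571 ± 0.31) and Mef2c (0.128 ± 0.053, 2 rows). The median was 0.611 RPKM, at percentile 50.5 (66.6 without replicate 3), and 1.78 RPKM at percentile 71.2 over the 11 members with 1 row. Among random lists drawn from genes of 0.1 RPKM or more, the full list stood at percentile 12. The counts adjusted over the list alone were 6 above and 2 below. With any library left out, 6 were above and 1 below.

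Gene pairs set some of these genes against each other. The osteoblast gene Alpl exceeded the osteocyte gene Dmp1 with a log2 ratio of Dmp1 over Alpl of −7.92 ± 1.54 (limma adjusted p = 0.0018), in 3 of 3 libraries. It was −7.05 without replicate 3, −6.38 with a pseudocount of 1 and −8.54 with the GC correction. Within the osteocyte list, Phex exceeded Fgf23 25.3-fold (log2 ratio of Fgf23 over Phex −4.66 ± 0.49, limma adjusted p = 0.000476), and the log2 ratio was −2.99 with a pseudocount of 1. Mepe and Dmp1 did not differ past the threshold (log2 ratio −0.09 ± 2.18, limma adjusted p = 0.933), and replicate 3 set that spread. Without it the ratio was −1.34 with a limma adjusted p of 0.0209. Per kilobase and over the pooled libraries, Dmp1 had 74 times the counts of Sost, with a counting interval of 20.2 to 615. All Sost counts came from replicate 1. The limma test of this pair gave an adjusted p of 0.0508, and 0.00585 without replicate 3, with a log2 ratio of −2.33 ± 1.57 that became −3.21. It was −2.08 without replicate 1, −1.69 without replicate 2 and −1.61 with the GC correction (limma adjusted p = 0.226, 0.192 and 0.124). The value with the GC correction says little, because in replicates 2 and 3 it shifts only the pseudocount of Sost.

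**Figure D1:**
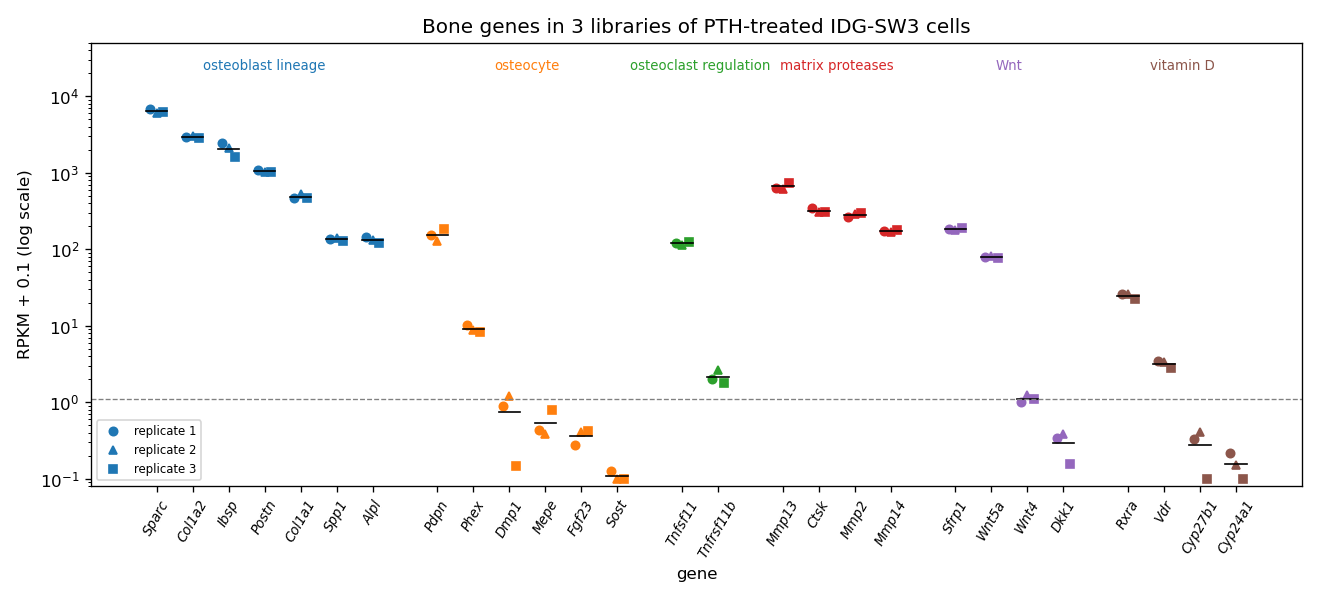
RPKM + 0.1 on a log axis for 27 bone genes, grouped by function, in the 3 libraries of PTH-treated cells (a marker shape per replicate, the horizontal bar is their mean, and the dashed line is 1 RPKM). Sparc, Col1a2 and Ibsp lie above 1000 RPKM, Tnfsf11 lies far above Tnfrsf11b, and Dmp1, Mepe, Fgf23 and Sost lie around or under the line, with Dmp1 lowest in replicate 3.

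Regulators of osteoclast formation were uneven. Tnfsf11, which encodes the osteoclast-forming cytokine RANKL, stood at 120.2 ± 6.14 RPKM. Tnfrsf11b, which encodes its decoy receptor osteoprotegerin, stood at 2.04 ± 0.442. Tnfsf11 exceeded Tnfrsf11b 56.8-fold (log2 ratio 5.83 ± 0.36, limma adjusted p = 0.000198), with log2 ratios of 5.93, 5.43 and 6.13 in the 3 libraries. With DESeq2 and its uncentred factors, Tnfrsf11b was no longer called above 1 RPKM (adjusted p = 0.411). Wisp1 stood at 201 ± 35.8 RPKM and the chemokine genes Cxcl12 and Ccl7 at 44.5 ± 6.24 and 33.7 ± 5.83. The list had 7 of 13 members above, 1 below, 4 unresolved and 1 at 0, also when adjusted over the list alone. Its median was 2.04 RPKM (percentile 84.9), and 8.80 RPKM (percentile 95.2) over 9 members with 1 row. The member below, Csf1, has 3 rows, and its level was 0.351 ± 0.237. The call was lost without replicate 1 or replicate 2 (edgeR adjusted p = 0.149 each). With the shortest transcript length the direction was reversed (log2 level against the threshold 0.146, edgeR adjusted p = 0.803). Il34, at 0, has 2 rows, so the size of the called ratio of Csf1 to Il34 is uncertain, and the call was lost without replicate 2 (limma adjusted p = 0.0843).

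Genes of perilacunar remodelling, the resorption of matrix by osteocytes, were broadly expressed, with 13 of 18 above 1 RPKM and a median of 40.4 RPKM (percentile 100). Mmp13, a collagenase, stood at 664 ± 72.1 RPKM, the protease inhibitor Timp3 at 564 ± 24.4, the collagen-degrading cathepsin gene Ctsk at 321 ± 24.5 and the gelatinase gene Mmp2 at 285 ± 18.6. Tcirg1 (3 rows) was below, 3 members were unresolved and Acp5 (3 rows) was listed at 0. When adjusted over the list alone, 13 were above and 1 below, and 0 were below with any library left out. Mmp13 exceeded the membrane-bound Mmp14 (174 ± 6.82 RPKM) 3.81-fold, with a log2 ratio of 1.93 ± 0.11 (limma adjusted p = 0.000473). The GC correction brought that ratio to 1.20. Ctsk was called higher than Acp5, but no fold is given because Acp5 has several rows.

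The PTH receptor pathway was represented by many G protein and protein kinase A genes. Of its 46 members, 20 were above 1 RPKM, 14 below, 8 unresolved and 4 at 0. All 20 that were above had 1 row. Prkar1a, a regulatory subunit of protein kinase A, stood at 84.3 ± 3.72 RPKM, and the G protein gene Gna13 at 78.4 ± 3.91. The phosphodiesterase gene Pde7b stood at 42.5 ± 4.63 and the catalytic subunit gene Prkaca at 23.3 ± 1.02. Pth1r, the PTH receptor gene, was listed at 1.04 ± 0.367 RPKM and was unresolved, and Pth2r stood at 0.329 ± 0.0815, called below, a call lost without replicates 1, 2 or 3 (edgeR adjusted p = 0.134, 0.166 and 0.0508). The log2 ratio of Pth1r to Pth2r was 1.38 ± 0.52 (limma adjusted p = 0.0127), and the call was lost without replicate 1 (0.0921) or replicate 2 (0.0843). It was also lost with the mean over rows (limma adjusted p = 0.905), which divides the counts of Pth1r by its 3 rows. Pth1r has 3 rows and Gnas, the stimulatory G protein gene, 9 rows (0.0711 ± 0.063 RPKM), so these low values are uncertain. The median was 0.644 RPKM (percentile 67.1), and 1.85 RPKM (percentile 85.4) over 35 members with 1 row. Among random lists drawn from genes of 0.1 RPKM or more, the full list stood at percentile 6.4. The counts adjusted over the list alone were 20 above and 15 below. The count below was 5 without replicate 1 or replicate 2, and 12 without replicate 3.

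Genes that respond to cyclic AMP, the second messenger of the PTH receptor, lay at moderate levels after 24 h. Above 1 RPKM were 17 of 29, with 2 below, 8 unresolved and 2 at 0, and the median was 3.04 RPKM (percentile 97.2). The transcription factor genes Cebpb and Fosl2 stood at 76.6 ± 16.0 and 36.7 ± 2.11 RPKM, Btg2 at 32.3 ± 2.53 and Cebpd at 31.0 ± 3.59. The immediate early gene Nr4a1 stood at 0.576 ± 0.306 and Nr4a2 at 0.0458 ± 0.0401, both unresolved, although the planned limma test called Nr4a2 below (limma adjusted p = 9.4e-06). The members below were Pde10a (0.407 ± 0.24) and Fosb (0.307 ± 0.024), and those at 0 were Crem (11 rows) and Per1 (2 rows). When adjusted over the list alone, 17 were above and 3 below. Without replicates 1, 2 and 3 the counts below were 1, 1 and 3. Pde4d (20.1 ± 2.76) exceeded Pde4b (6.81 ± 0.669, 5 rows) with a log2 ratio of Pde4b over Pde4d of −1.54 ± 0.06 (limma adjusted p = 0.000566). The ratio depended on the lengths taken, at −0.37 with the shortest transcripts. It was −3.78 with the mean over rows, which divides the counts of Pde4b by its 5 rows. After the same division, the level of Pde4b was not called (edgeR adjusted p = 0.0777). Prkaca exceeded Prkacb (4 rows) and Nr4a1 exceeded Nr4a2 (2 rows) with log2 ratios of 4.86 ± 0.31 and 2.15 ± 0.31, for which the row numbers leave the size uncertain (limma adjusted p = 0.000198 and 0.00128).

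Wnt pathway genes included abundant members of secreted antagonist families. The list had 23 of 42 members above 1 RPKM, 3 below, 15 unresolved and 1 at 0, with a median of 2.17 RPKM (percentile 97.2). Sfrp1 stood at 186 ± 5.93 RPKM, the receptor gene Fzd1 at 180.0 ± 13.4, Sfrp2 at 153 ± 29.4 and Dkk3 at 134 ± 3.30. The ligand gene Wnt5a (79.3 ± 1.55) exceeded Wnt4 (1.02 ± 0.129) 71.5-fold, with a log2 ratio of Wnt4 over Wnt5a of −6.16 ± 0.15 (limma adjusted p = 7.98e-05). It was −5.26 with the GC correction and −5.32 with a pseudocount of 1. Dkk1 was unresolved at 0.196 ± 0.124 RPKM, but was called below by the planned limma test (limma adjusted p = 0.003) and by edgeR without replicate 3 (adjusted p = 0.049). Over the pooled libraries, Dkk1 had 22.6 times the counts of Sost per kilobase, with a counting interval of 5.94 to 191. All Sost counts came from replicate 1. The limma call of this pair (adjusted p = 0.0254) was lost without replicate 1 (0.145) or replicate 2 (0.0934) and with the GC correction (0.492). The loss with the GC correction says little, because in replicates 2 and 3 it shifts only the pseudocount of Sost. The members below were Fzd4, Lgr6 and Wnt11, and their number was 2 without replicate 1 or replicate 2. When adjusted over the list alone, 23 were above and 4 below. Over the 36 members with 1 row the percentile was 94.8.

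The vitamin D receptor pair and the hydroxylase gene Cyp2r1 (2.34 ± 0.65 RPKM) were above 1 RPKM, whereas the hydroxylase genes Cyp24a1 and Cyp27b1 were unresolved. The planned limma test called both below 1 RPKM (limma adjusted p = 2.54e-05 and 0.00297). Rxra stood at 24.7 ± 2.22 RPKM and the vitamin D receptor gene Vdr at 3.09 ± 0.326, a log2 ratio of Vdr over Rxra of −2.96 ± 0.02 (limma adjusted p = 0.000173), which was −2.05 with the longest transcripts and −3.64 with the GC correction. With DESeq2 and its uncentred factors, Vdr was not called above 1 RPKM (adjusted p = 0.0617). Pdia3 stood at 108 ± 6.82, the calcium pump gene Atp2b1 at 33.8 ± 2.45 and the corepressor gene Ncor1 at 9.57 ± 0.369. Cyp24a1, which inactivates vitamin D, had 15, 7 and 0 counts, and Cyp27b1, which activates it, 19, 27 and 0. Their ratio did not pass the test (log2 −0.66 ± 0.71, limma adjusted p = 0.146), and 2 of 3 libraries had less Cyp24a1. With the GC correction it was −1.13 and passed (limma adjusted p = 0.0428). That pass is not read as a difference, because both genes had 0 counts in replicate 3, where the correction shifts only pseudocounts. The list had 8 of 17 members above, 0 below, 8 unresolved and 1 at 0, with a median of 1.06 RPKM (percentile 74.9, and 34.4 among lists from genes of 0.1 RPKM or more). The counts were the same when adjusted over the list alone, with 1, 1 and 2 below without replicates 1, 2 and 3.

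Phosphate and mineral genes had 11 of 22 members above 1 RPKM, 3 below, 7 unresolved and 1 at 0, also when adjusted over the list alone. The count below was 1 without replicate 1 or replicate 2. The median was 1.22 RPKM (percentile 73.5, 82.1 without replicate 3, and 26.5 among lists from genes of 0.1 RPKM or more). Mgp, an inhibitor of mineralization, stood at 156 ± 10.1 RPKM. The phosphate transporter genes Slc20a1 (2 rows), Xpr1 and Slc20a2 stood at 20.99 ± 0.537, 13.3 ± 1.39 and 9.12 ± 0.539. Ank, a gene of pyrophosphate export, stood at 11.5 ± 1.36 and exceeded Enpp1, which makes pyrophosphate (3.08 ± 0.486), 3.67-fold with a log2 ratio of Enpp1 over Ank of −1.88 ± 0.37 (limma adjusted p = 0.00238). The ratio was −1.09 with the shortest transcripts, and DESeq2 with uncentred factors did not call Enpp1 above 1 RPKM (adjusted p = 0.0652). Slc20a1 exceeded Slc20a2 with a log2 ratio of 1.20 ± 0.11 (limma adjusted p = 0.0014). With the mean over rows the ratio was 0.20 (limma adjusted p = 0.141), a fall that dividing the counts of Slc20a1 by its 2 rows produces. The members below were Kl, Slc34a1 and Slc34a2, the last 2 being phosphate transporter genes known from kidney and gut epithelia.

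Cytoskeleton, dendrite and junction genes had 15 of 23 members above 1 RPKM, 4 below and 4 unresolved, and a median of 23.2 RPKM (percentile 100). Besides Gja1, the actin genes Actb and Actg1 stood at 1576 ± 105 and 275 ± 27.7 RPKM and the integrin gene Itgb1 at 652 ± 39.9. Gjc1 was listed at 0.192 ± 0.140, unresolved with edgeR and below with the planned limma test (limma adjusted p = 0.00283). It has 3 rows, so its called ratio to Gja1 (limma adjusted p = 0.000161) has an uncertain size. The members below were Panx1, Lcp1, and, with 3 rows each, Pls3 and Rdx. The counts adjusted over the list alone were 15 above and 5 below, and 1, 0 and 2 were below without replicates 1, 2 and 3. In all, 19 of the 22 gene pairs passed the limma test, and 11 of the 14 pairs whose members both have 1 row.

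Cell cycle transcripts were present in these late cultures, with 13 of 20 above 1 RPKM, 0 below, 6 unresolved and 1 at 0. The median was 2.20 RPKM (percentile 91.6). The replication genes Pcna and Mcm2 stood at 23.4 ± 1.11 and 14.1 ± 0.404 RPKM, the topoisomerase gene Top2a at 9.45 ± 1.83 and Rrm2 at 6.37 ± 0.898. Interferon response genes had 13 of 21 members above, 2 below and 6 unresolved, with a median of 5.47 RPKM (percentile 99). B2m stood at 117 ± 6.75 RPKM, Ifit3 at 32.0 ± 3.04 and the immunoproteasome gene Psmb8 at 26.6 ± 4.69. The interferon members below were Mx1 and Ciita. The cell cycle counts were the same when adjusted over the list alone, and the interferon counts were 13 above and 3 below, with 1 below without replicate 1 or replicate 2.

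Markers of cell types other than bone were mostly low. The muscle list had 1 of 12 above, 5 below, 5 unresolved and 1 at 0, with a median of 0.126 RPKM (percentile 4). Actn3 was highest there at 1.52 ± 0.591, a call lost without replicate 2. The endothelial list had 1 of 10 above, 2 below, 5 unresolved and 2 at 0, with a median of 0.0759 (percentile 1.4), and Kdr at 2.62 ± 0.185. The macrophage and osteoclast list had 1 of 12 above, 3 below, 6 unresolved and 2 at 0, with a median of 0.104 (percentile 2.7). The member above was Lyz2, a lysozyme gene, at 12.9 ± 1.098, whereas Cd68 stood at 0.767 ± 0.62. The neuronal list had 1 of 9 above, 2 below and 6 unresolved, with a median of 0.279 (percentile 20.5), and Tubb3 at 2.84 ± 0.581. The haematopoietic list had 0 of 9 above, 2 below and 7 unresolved, with a median of 0.0613 (percentile 1.2). These percentiles depended on the libraries kept. The endothelial one was 4.9 without replicate 3, the haematopoietic one 3.2 without replicate 1 or replicate 2, the muscle one 2.1 without replicate 2 and 5.6 without replicate 3, and the neuronal one 12.6 without replicate 2. In replicate 3 alone the endothelial and haematopoietic medians were 0.

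Adipocyte and chondrocyte lists lay closer to the osteocyte list. Fabp4, Lpl and Adipoq, fatty acid and adipokine genes, stood at 9.72 ± 3.19, 3.79 ± 0.318 and 1.88 ± 1.16 RPKM, and were the 3 of 12 adipocyte members above, with 1 below, 7 unresolved and 1 at 0. The adipocyte median was 0.409 RPKM (percentile 39.5, and 6 among lists from genes of 0.1 RPKM or more). Comp, a cartilage matrix gene, stood at 49.9 ± 10.9 RPKM, Sox9 at 4.17 ± 1.17 and Col10a1 at 3.90 ± 0.787, and these were the 3 of 11 chondrocyte members above, with 4 below and 4 unresolved. The chondrocyte median was 0.530 RPKM (percentile 54, and 17.9 among such lists). When adjusted over each list alone, the counts above were the same in these 7 lists, and those below were 5 for chondrocyte, 1 for neuronal and 0 for haematopoietic genes and otherwise the same. Without replicate 1, 0 chondrocyte and 0 haematopoietic genes were below, and without replicate 3, 2 adipocyte genes were above.

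Across genes, the osteocyte list lay above 3 of the 7 lists of other cell types on the log2(RPKM + 0.1) scale. The comparison is of list means, which Pdpn (156 RPKM) and Hyou1 (43.8 RPKM) raise, whereas the osteocyte list's median was only 0.611 RPKM. No comparison was run without these genes. The osteocyte list was 7.45-fold above the muscle list (permutation test, adjusted p = 0.0186). It was 9.45-fold above the haematopoietic list (permutation adjusted p = 0.0186) and 6.60-fold above the endothelial list (permutation adjusted p = 0.0471). Against macrophage and neuronal genes the folds were 5.10 and 5.33 (permutation adjusted p = 0.062 each). The folds over adipocyte and chondrocyte genes were 2.69 and 1.89 (permutation adjusted p = 0.23 and 0.442). With a pseudocount of 1, 0 of the 7 permutation comparisons passed after adjustment and 3 had an unadjusted p under 0.05. The endothelial call was lost without replicate 1 (permutation adjusted p = 0.0514), with the highest row kept (0.0583) and with members above 0 only (0.105). The macrophage and neuronal comparisons passed without replicate 3 (permutation adjusted p = 0.0492 each).

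**Figure D2:**
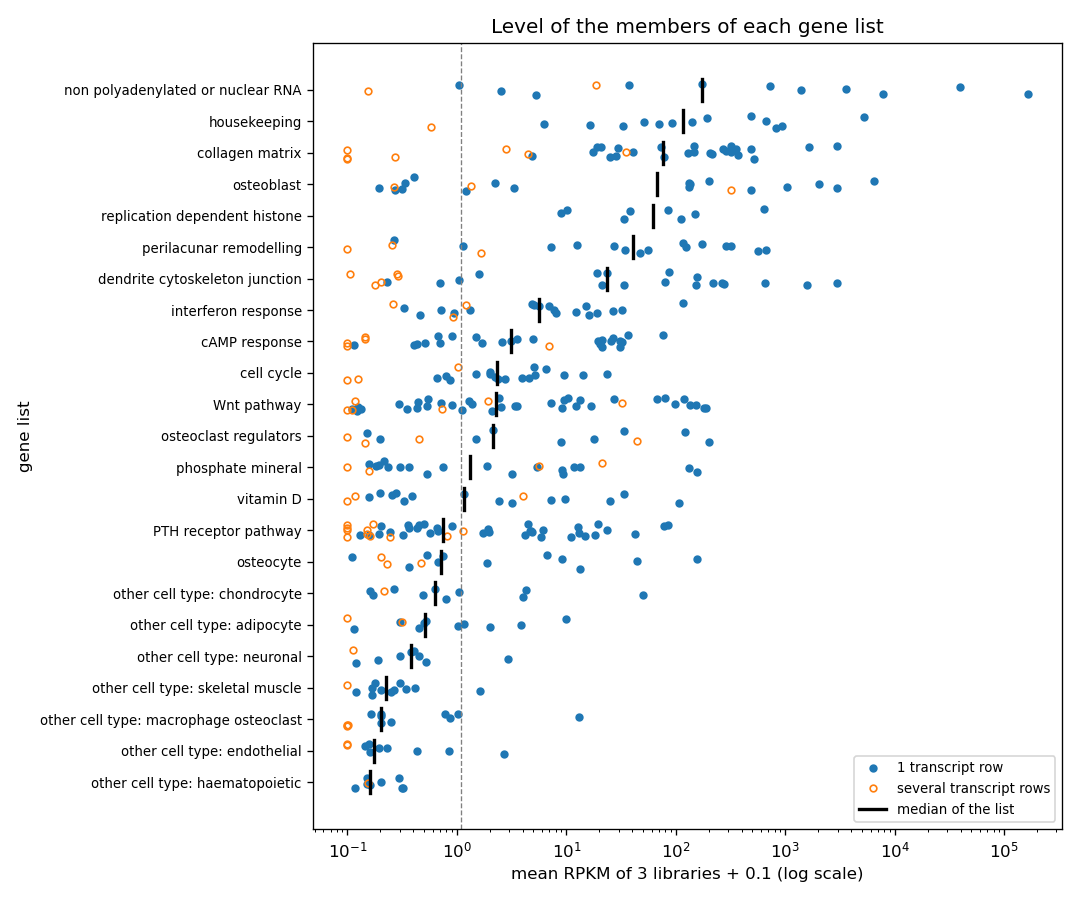
Mean RPKM of 3 libraries + 0.1 on a log axis for the members of each gene list, with filled points for symbols with 1 transcript row, open points for symbols with several, a black bar at the list's median and a dashed line at 1 RPKM. Matrix, osteoblast and remodelling lists have medians of 40.4 to 75.6 RPKM, lists of other cell types have medians of 0.0613 to 0.530 RPKM, and many open points lie at the left edge.

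Control and RNA class lists were high. Of the housekeeping genes 13 of 14 were above 1 RPKM, 0 were below and 1 was unresolved, with a median of 116 RPKM (percentile 100). Rplp0 stood at 938 ± 27.6 RPKM and Pgk1 at 663 ± 53.7. Gapdh stood lower, at 32.6 ± 4.3, and sequence that it may share with other genes was not examined. The 8 histone genes measured, whose mRNAs mostly lack a poly(A) tail, were all above 1 RPKM, with a median of 61.5 RPKM (percentile 100). Hist2h2aa1 stood at 644 ± 129 RPKM, Hist1h2ab at 149 ± 33.3, Hist1h1c at 110.4 ± 5.37 and Hist1h2bc at 85.2 ± 2.92. Histone copies are near-identical, so the split among them is uncertain. Noncoding and nuclear RNAs had 11 of 13 above, 0 below and 2 unresolved, with a median of 174 RPKM (percentile 100). Rn7sk, which restrains transcription elongation, took 5.04%, 6.16% and 5.15% of the counts in replicates 1, 2 and 3, and Malat1 took 2.38%, 2.69% and 2.06%. Malat1 is given as a share because the median of its annotated transcripts, 606 nt, is far shorter than the full transcript. Rmrp stood at 7854 ± 1572 RPKM and Rpph1 at 3593 ± 962. The counts of these 3 lists were the same when adjusted over each list alone.

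Restricting the other lists to symbols with 1 row raised most medians. The median became 131.2 RPKM for osteoblast, 146 for collagen, 55.81 for remodelling, 83.08 for cytoskeleton and junction, 139.3 for housekeeping and 726 for noncoding and nuclear RNA genes, each again at percentile 100. It became 4.149 RPKM (percentile 95.7) for cyclic AMP response, 2.838 (94.8) for Wnt, 1.701 (72.3) for vitamin D, 2.63 (83.7) for cell cycle and 7.211 (98.8) for interferon response genes, and stayed at 1.216 (60.2) for phosphate genes. Among the lists of other cell types it became 0.6731 RPKM (percentile 45.1) for adipocyte, 0.6084 (45.4) for chondrocyte, 0.1502 (3.5) for muscle, 0.11 (1.9) for endothelial, 0.1517 (8.3) for macrophage and osteoclast, 0.2933 (12.4) for neuronal and 0.08196 (0.4) for haematopoietic genes. All 8 histone genes have 1 row.

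The small nuclear RNA genes Rnu2 and Rnu1b6 were also among the 15 highest symbols, at 30798 ± 9668 and 8116 ± 1385 RPKM, although molecules this short are captured unevenly. Others among the 15 were copies of ribosomal protein or histone H3.3 genes. H3f3c, Gm12657 and Gm6421 stood at 6258 ± 964, 6018 ± 977 and 6008 ± 957 RPKM, and their counts in each library were close to those of H3f3a. Of their 50-nt words, 73.8%, 72.1% and 58.3% also occur in transcripts of other genes, so these levels are uncertain. The same holds for Gm10119 (90.2% shared), Gm4332 (89.9%), Gm2000 (85.1%) and Gm10269 (54.5%), which stood between 3902 and 6951 RPKM.

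Replicates ranked genes alike. Across genes, Pearson's r of log2(RPKM + 0.1) was 0.9676, 0.9608 and 0.9639 for the 3 pairs of libraries, and Spearman's rho 0.9204, 0.9082 and 0.9126; genes are not independent replicates. The median SD was 0.17 on the log2 scale over 9869 genes with mean RPKM of 1 or more. It was 0.11 above 100 RPKM and 0.71 between 0.1 and 1 RPKM, so low levels carry large errors. The 10 genes with the largest SD were mostly short RNAs, among them Rprl1 (0, 4500 and 32 counts), Mir677, Snora31, Snora28, Snord35b, Snord22 and Rny1. The others were 1700120B22Rik, Gm10046 and Flg (52, 329 and 230 counts).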

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

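The tests with DESeq2, the mean over rows, other transcript lengths, counts per 1000000 (CPM), symbols with 1 row and the GC correction were chosen after the data were seen. The count of genes above 1 RPKM ranged from 7465 (DESeq2) to 10426 (1 CPM, no length) over all alternatives run, within 1.5 times the reported 9071. The count below, 2807, moved widely. It was 9842 with the planned limma test on log2(RPKM + 0.1). Variants of that limma test gave 9875 with a pseudocount of 1, 9877 with a pseudocount of 0.01, and 9269 without trend or robust estimation. DESeq2 with uncentred factors gave 267. With edgeR the count was 4338 with no filter, 1370 with libraries rescaled to a total of 1000000 and 469 against 0.5 RPKM. It was 0 against 1 CPM (with 175 at an unadjusted edgeR p under 0.05). Without each replicate in turn it ranged from 907 to 2559. The cause was not tested. Csf1, called below, stood at 0.15 on the log2 scale relative to the threshold with the shortest transcript length (edgeR adjusted p = 0.803), since a shorter length raises its RPKM. Among the named genes' levels, 612 other values kept direction and side of the threshold, 44 passed it and 19 no longer did.

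Gene pair ratios passed in 19 of 22 cases and in 11 with symbols with 1 row, where only 14 pairs remain. Over the other alternatives 16 to 21 passed. The comparisons of the osteocyte list passed for 3 of 7 lists, for 0 with a pseudocount of 1 (3 at an unadjusted permutation p under 0.05) and for 5 with a pseudocount of 0.01. They passed for 2 to 5 lists when each replicate was left out in turn; the cause was not tested. Lists above percentile 95 numbered 10, also without each replicate, and 7 when random lists were drawn from genes of 0.1 RPKM or more, where the cyclic AMP, Wnt and interferon lists stood at percentiles 77.6, 66.1 and 91.7. That choice lowered other lists as well, to 12 for osteocyte, 6.4 for PTH pathway, 58 for osteoclast regulator, 34.4 for vitamin D, 26.5 for phosphate, 61.7 for cell cycle and 1 for neuronal genes, since it leaves unexpressed genes out of the random lists. Leaving out a library moved further percentiles, the osteocyte list from 50.5 to 66.6, the phosphate list from 73.5 to 82.1 and the endothelial list from 1.4 to 4.9 without replicate 3, the haematopoietic list from 1.2 to 3.2 without replicate 1 or replicate 2, and the neuronal list from 20.5 to 12.6 and the muscle list from 4 to 2.1 without replicate 2 and to 5.6 without replicate 3. The lowest Pearson r between libraries, 0.9608, was 0.9892 with a pseudocount of 1 and 0.9053 with a pseudocount of 0.01, which weigh low genes less and more, and ranged from 0.9608 to 0.9676 without each replicate. Low levels were the least certain, with a median SD of 0.71 on the log2 scale between 0.1 and 1 RPKM against 0.11 above 100 RPKM.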

Other observations

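Gene families that the comparisons above leave out were described after their values were seen. Of 32 endoplasmic reticulum chaperones and transport factors, 27 were above 1 RPKM by the edgeR test, 3 were unresolved and 2 were at 0. Among the highest besides Hsp90b1 and P4hb, Ssr3 of the translocon stood at 1129 ± 82.2 RPKM, Pdia4 at 1111 ± 54.1, the vesicle cargo receptor gene Tmed2 at 1003 ± 116 and the calcium-binding chaperone gene Calr at 962 ± 16.98. Chemokine genes had 10 of 36 members above, led by Cxcl14 at 342 ± 4.41 RPKM, with Cxcl1 at 31.1 ± 4.97 and Cx3cl1 at 17.9 ± 0.646. Genes of insulin-like growth factor binding proteins had 5 of 7 above, with Igfbp4 at 797 ± 62.8 and Igfbp5 at 169 ± 24.2, and Igfbp7, which has 2 rows, listed at 0. CCN genes, which encode matricellular proteins, had 5 of 6 above, with Wisp2 at 369.6 ± 11.9 and Nov at 87.5 ± 11.2.

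Among growth factor ligands of the Bmp, Gdf, activin and Tgfb families, 12 of 28 were above 1 RPKM, with Tgfb3 at 55.3 ± 2.77, Inhbb at 33.7 ± 2.14, Tgfb2 at 32.6 ± 5.95 and Bmp4 at 21.7 ± 1.04. Fgf ligands had 4 of 22 above, and Fgf7 stood at 121 ± 5.33 RPKM against 5.90 ± 1.62 for Fgf2. Of the matrix proteases, 17 of 40 Mmp and Adamts genes were above and 12 below, with Adamts1 at 201 ± 8.20 RPKM and Mmp3 at 51.0 ± 4.28. Hox genes, which mark body position, were mostly unresolved against 1 RPKM. Only Hoxd8 (13.8 ± 1.75), Hoxa11 (3.25 ± 0.914) and Hoxa9 (2.94 ± 0.667) of 39 passed as above 1 RPKM, with 31 unresolved.

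In the tests that follow, those of isoform number, of counts split among rows, of the row numbers of osteocyte genes and of the hormone were chosen before their result was seen, and the others after. Symbols with several transcript rows lay near 0. Among protein-coding genes 31.8% of them were at 0 in all 3 libraries, against 2.7% of those with 1 row. A candidate explanation is that reads shared by several rows of a gene were left out of the counts. Families that every cell uses were compared (proteasome, respiratory chain, mitochondrial ribosome, splicing, transcription and translation initiation). Of their 32 members with several rows 40.6% were above 1 RPKM, against 93.2% of 251 members with 1 row (Fisher's exact test, p = 7.59e-12). The explanation needs such a gap. The gap restates the pattern among widely used genes, however, and does not single out shared reads. A lower expression of genes with several isoforms is not settled. Among protein-coding symbols with 1 row, those with 3 or more annotated transcripts had a median 2.55 times that of symbols with 1 transcript. That argues against such an effect among symbols with 1 row, but does not cover those with several. No biological explanation beyond that was tested.

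Low counts varied widely between libraries, and replicate 3 listed 19560 symbols above 0 against 20763 and 21542 in replicates 1 and 2. Lower depth is argued against, because replicate 3 had the most counts, 45240005 (45.2 in units of 1000000). Splitting of counts among rows is argued against as the whole cause, since the pattern held over symbols with 1 row, which cannot be split: their ratio of variance to mean was 9.89 at mean counts of 5 to 10, and of those with an expected count of 5 to 10, 44.8% were at 0 in replicate 3 against 25.7% and 19.5% in replicates 1 and 2. The ratio of variance to mean at mean counts of 50 to 100 was 1.24 times that at 5 to 10, with a 95% bootstrap interval over genes of 1.17 to 1.32. Variation between cultures with the same relative spread at every level is argued against as the whole cause, since it would have given 8.77. Copies of single molecules made by amplification would give a nearly level ratio, but so would variation between cultures whose relative spread falls as expression rises. With 1 library per culture these 2 remain open, as does the chance that the values are another whole-number quantity than counts of reads.

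Mean levels of Dmp1, Sost, Mepe and Fgf23 lay under 1 RPKM in cells labelled osteocytic, beside abundant Tnfsf11, Mmp13 and Pdpn. The edgeR test left all 4 unresolved against 1 RPKM. Lists of other cell types had medians of at most 0.53 RPKM, but the osteocyte list's own median was only 0.611 RPKM. Low list medians alone therefore cannot decide whether cells of another type stood in place of osteocytes. The osteoblast list, however, had a median of 67.2 RPKM, with 12 of 20 members above 1 RPKM, 2 below and 6 unresolved. That argues against cells of the 7 listed types standing in place of osteoblast-lineage cells, and does not cover osteocytes. No fibroblast list was among the 7. A loss of the osteoblast lineage programme as a whole is argued against by the osteoblast list at percentile 100. A loss of part of that programme stays open, since the osteoblast members Ifitm5 (0.307 ± 0.224 RPKM), Msx2 (0.237 ± 0.216), Smpd3 (0.218 ± 0.193), Dlx3 (0.170 ± 0.179), Dlx5 (0.164 ± 0.205, 2 rows) and Phospho1 (0.0942 ± 0.094) were low as well. Counts lost among rows are argued against for these genes, since 4 of 4 have 1 row. Whether the hormone may have lowered them is left open, because 0 vehicle libraries were in the data used. A low state before treatment is equally untested.

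Counts of the 18S ribosomal RNA symbol Rn18s were 11195, 90889 and 12561 in replicates 1, 2 and 3, or 0.032%, 0.244% and 0.028% of the library.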
